A study of Mus musculus with 27 samples.

How the data were processed

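RNA of primary mouse lung fibroblasts was extracted and prepared with TruSeq kits, per the labels' protocols. The raw read counts per gene deposited by the authors were made with featureCounts on mm10, per the submitters' processing notes. The aligner, the annotation release, the versions and whether counting used the strand are not given in the sources used here, so values of overlapping or antisense genes and of near-identical gene copies are uncertain. The authors also deposited TPM values for the same libraries, and a TPM table of expressed genes with the same values for 15372 genes, each of at least 1 TPM in 3 or more libraries. The deposited count table held 48440 genes and that of TPM values 48082 genes. Symbols were found for 48058 gene IDs, and 40606 versioned IDs (83.8%) are in GENCODE M21, whose GRCm38 positions, gene types and lengths were used. Groups and replicate numbers were taken from the sample titles, and each table column was matched to a sample by its title.

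Genes were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test with robust dispersions, TMM scaling, filterByExpr with a minimum count of 10) in 1 group-means model of all 27 libraries, which left 18684 genes. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, and adjusted p-values of genes in the text are edgeR's unless another tool is named. Standard errors are the log2 fold change divided by the square root of F and so approximate. Of the 10 planned comparisons, 5 set a treated group against its DMSO group, 3 test differences between KU60019 effects and 2 compare DMSO groups. Another 4 comparisons, the arms of the removal differences, were added after the data were seen.

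The 25 gene lists, written down before the data were examined, cover mitosis, DNA replication, p53 targets, DNA damage response and repair, senescence regulators, the secretory phenotype of senescent cells, interferon response, lysosome and autophagy, oxidative stress, aryl hydrocarbon receptor targets, glycolysis, oxidative phosphorylation, cholesterol and fatty acid synthesis, endoplasmic reticulum stress, extracellular matrix, contractile genes, immediate early genes, mitochondrially encoded RNAs and markers of macrophages, epithelium, endothelium, mesothelium, pericytes, adipocytes and chondrocytes. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and each adjusted p beside a list is camera's. Members rose or fell by the test over all genes or, within the list, adjusted over its members alone.

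Genes were named by a rule set at the same time: a panel of 7, the 6 largest rises and 6 largest falls of a main comparison (5 and 5 elsewhere) among genes with adjusted p under 0.05, a mean of at least 5 CPM in the higher group and, except for differences, no overlap of libraries, and list members among the 4 with the lowest p. The absence of overlap has a chance of 10% per gene with 3 against 3. Some genes that met this rule are not reported here. Predicted and clone-based names were excluded, and that pattern was widened after the clone name U90926 had been seen as a top rise in DMSO culture. Counts of 0 in a group were set against a floor of 3 counts over the group, and ratios from 1 to 3 counts carry 95% exact intervals that cover counting error only.

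On simulated data for the 15 d KU60019 comparison (18684 genes), edgeR recovered 10.4%, 53.7% and 81.8% of genes changed 1.5-, 2- and 4-fold, with 6 unchanged genes called (5.83% of calls). DESeq2 1.42.0 recovered 23.9%, 58.2% and 84.8% with 29 (20.7%), and limma on TPM 13.4%, 53.7% and 87.9% with 14 (12.0%). Few simulated genes changed, so the threshold is stricter than in real data. Preset and estimated correlation and fry found a raised list and called 0 of 25 unchanged ones. Depth and correlation in lists were not varied, so their effect on preset calls is untested.

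Alternatives set before the data were examined were RLE size factors, library size alone, no filter on low counts, DESeq2, the replicate number as a block, only the compared groups in the fit, limma on log2(TPM + 1) for genes of at least 1 TPM in 3 libraries, each library left out, other controls for irradiation, an estimated correlation and fry for the lists. After the data were seen, fits with each library's trend of level with gene length removed, with protein-coding genes alone and without the 4 libraries above 0.4% rRNA were added. No 2 replicates of a group agreed within sampling noise (lowest chi-square per gene 7.18). Same-numbered libraries deviated together in the 15 d KU60019 comparison (r from 0.22 to 0.39), which met the rule for pairing, and did not in every pair of the other comparisons. The blocked counts of calls had been seen before that was written down. What the numbers stand for is not given in the sources used here.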

Results

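Total RNA was sequenced from 27 libraries of primary lung fibroblasts of wild-type C57BL/6 mice, 3 in each of 9 groups. Cells were kept for 15 or 35 d with 3 uM KU60019, an inhibitor of the DNA damage kinase ATM, or with the vehicle DMSO. Further groups had either treatment taken away and were harvested 20 d later. A last group received 10 Gy of X-rays and was harvested after 10 d, named in the series design as a positive control for senescence. Counts per library came to between 20659745 (DMSO 35 d then removed, S19_705) and 50859493 (DMSO 35 d, S15_716), with a median of 31265114. Libraries are named S1_705 to S27_716 in their titles, and every group has 1 library of each of the 3 end numbers. Nothing in the labels says whether these mark separate animals or cultures, so the p-values may measure only the spread between these samples. Levels below are CPM (counts scaled to library size times its TMM factor, mean ± SD, n = 3 per group) and log2 fold changes carry ± SE.

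Atm encodes the kinase that KU60019 blocks (ENSMUSG00000034218, chromosome 9, 53439149 to 53536740, minus strand). Cdkn1a encodes the cell cycle inhibitor p21 (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727, plus strand). Cdkn2a encodes the inhibitors p16 and p19ARF (ENSMUSG00000044303, chromosome 4, 89274471 to 89294653, minus strand) and Mdm2 the ubiquitin ligase of p53 (ENSMUSG00000020184, chromosome 10, 117688875 to 117710758, minus strand). Mki67 marks proliferating cells (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361, minus strand). Lmnb1 encodes the nuclear envelope protein lamin B1 (ENSMUSG00000024590, chromosome 18, 56707813 to 56753424, plus strand) and Il6 an inflammatory cytokine (ENSMUSG00000025746, chromosome 5, 30013114 to 30019981, plus strand). All 7 are protein coding and positions are on GRCm38 (mm10).

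**Figure D1:**
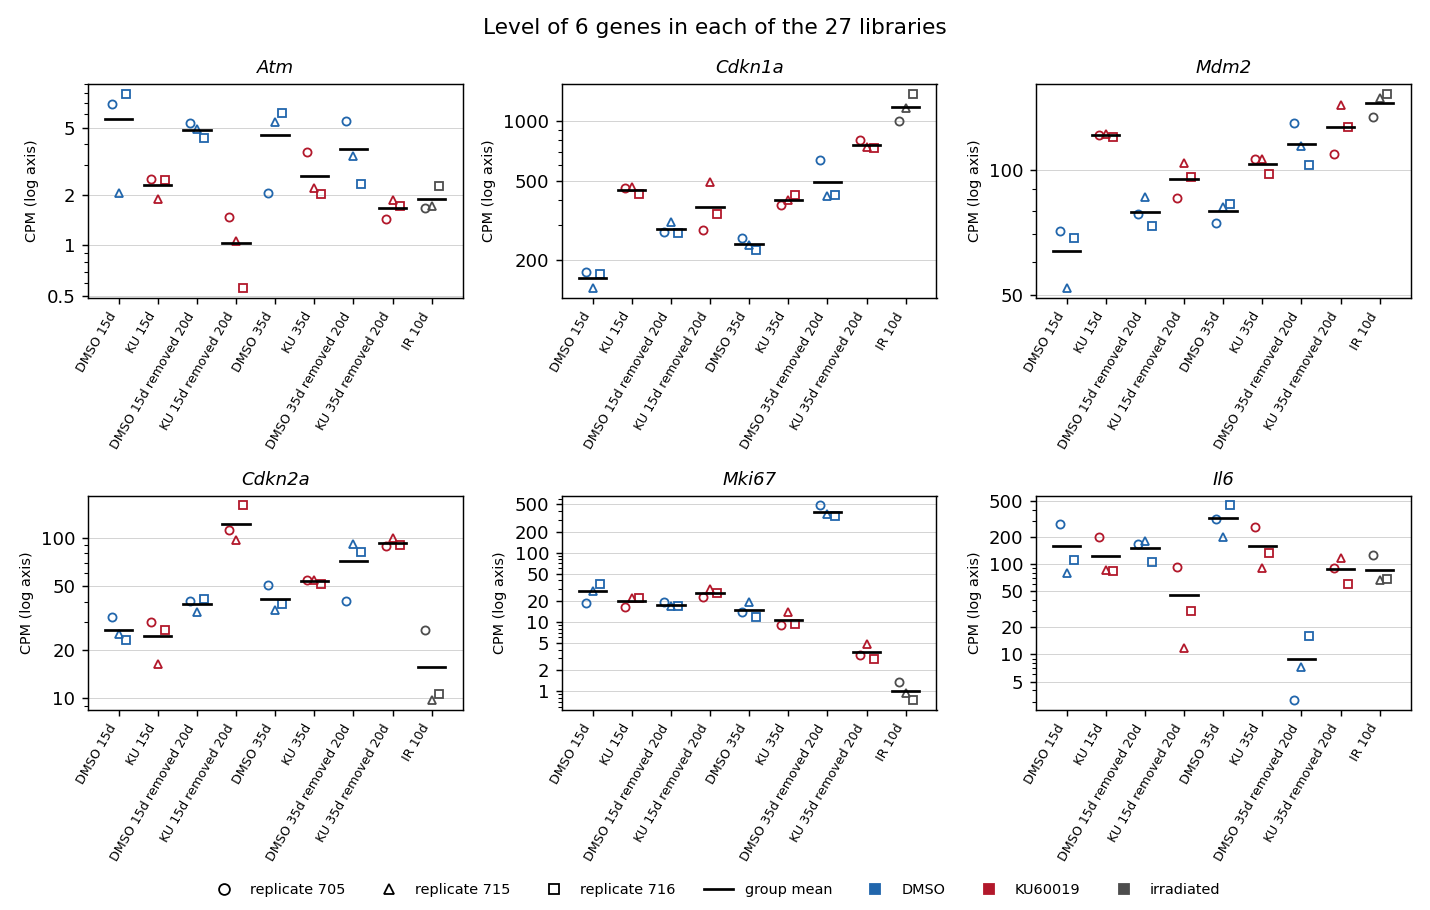
CPM (log axis) of Atm, Cdkn1a, Mdm2, Cdkn2a, Mki67 and Il6 in each of the 27 libraries, with points for libraries and bars for group means of 3. Mki67 lay highest in the DMSO group of 35 d plus removal, at 392 ± 77.2 CPM, and lowest after irradiation, at 1.01 ± 0.301 CPM.

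After 15 d of KU60019, fibroblasts had more RNA of p53 target and interferon response genes and less of extracellular matrix genes than after 15 d of DMSO, of which the p53 call alone held with an estimated correlation. Cdkn1a rose from 163 ± 15.9 to 451 ± 19.8 CPM (log2 fold change 1.47 ± 0.18, adjusted p = 3.27e-06) and Mdm2 by 0.93 ± 0.13 on the log2 scale. Atm itself fell (log2 fold change -1.32 ± 0.42, adjusted p = 0.0209). The collagen gene Col3a1 fell from 16338 ± 4787 to 1647 ± 413 CPM (-3.31 ± 0.37). Mki67 (-0.44 ± 0.23, adjusted p = 0.158), Lmnb1 (-0.43 ± 0.17, adjusted p = 0.0606), Cdkn2a (-0.14 ± 0.31, adjusted p = 0.772) and Il6 (-0.35 ± 0.62, adjusted p = 0.698) did not pass. In all, 5658 of 18684 genes changed, 2463 upward and 3195 downward, and among them 957 rose and 1628 fell at least 2-fold. On TPM 1079 rose and 3395 fell.

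The largest rise was that of Akr1c18, a progesterone-inactivating hydroxysteroid dehydrogenase (chromosome 13, 4132615 to 4150654, minus strand), from 0.283 ± 0.119 to 70.4 ± 3.28 CPM (log2 fold change 7.88 ± 0.60, adjusted p = 1.64e-08). S100a8, a subunit of calprotectin, rose by 7.42 ± 0.40, Ivl, which encodes involucrin of the cornified envelope, by 7.20 ± 0.77, and Crct1 of the epidermal differentiation complex by 7.20 ± 0.63. The proliferin genes Prl2c2 (6.33 ± 0.88) and Prl2c3 (6.28 ± 0.91) rose too, with their separate values uncertain because near-identical copies may share reads. Large falls were those of Wfdc21 (-6.07 ± 1.05), complement C7 (-5.72 ± 1.05), Ces1g, a carboxylesterase (-5.28 ± 0.64), Lyve1, a hyaluronan receptor of lymphatic endothelium and some macrophages (-4.84 ± 1.04), and Itih3 (-4.79 ± 0.49).

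Of the p53 targets, 19 of 29 rose and 1 fell (19 and 1 adjusted over the list alone, adjusted p = 8.75e-08, p = 0.00430 with an estimated correlation). Perp (3.37 ± 0.32) and Pmaip1 (2.70 ± 0.32), both pro-apoptotic, rose and Sesn1 fell (-1.35 ± 0.17). Of the interferon response genes, 36 of 39 rose and 0 fell (38 and 0 within the list, adjusted p = 2.37e-21, p = 0.174 at estimated correlation). Their median log2 fold change was 1.86. Usp18, which removes ISG15 from proteins, rose by 3.80 ± 0.46 and the GTPase gene Irgm1 by 2.73 ± 0.31. Contractile genes were called higher: 11 of 15 rose and 1 fell (11 and 2 within the list, adjusted p = 2.19e-04, p = 0.284 at estimated correlation). Examples were Ccn2, a matricellular protein gene (2.92 ± 0.29), and smooth muscle actin Acta2 (1.28 ± 0.26). For extracellular matrix genes, 16 of 29 fell and 1 rose (17 and 1 within the list, adjusted p = 1.28e-06, p = 0.196 at estimated correlation), and Col1a2 dropped by 2.09 ± 0.17.

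Immediate early genes moved up: 11 of 15 rose and 0 fell (11 and 0 within the list, adjusted p = 6.92e-06, p = 0.284 at estimated correlation). So did lysosome and autophagy genes, where 13 of 30 rose and 2 fell (13 and 2 within the list, adjusted p = 1.36e-04, p = 0.174 at estimated correlation). Of the glycolysis genes, 7 of 16 rose and 1 fell (8 and 2 within the list, adjusted p = 0.0132, p = 0.284 at estimated correlation). Among DNA replication genes 5 of 29 rose and 0 fell (4 and 0 within the list, adjusted p = 0.0394, p = 0.434 at estimated correlation). Among oxidative phosphorylation genes 4 of 32 rose and 0 fell (4 and 0 within the list, adjusted p = 0.00310, p = 0.434 at estimated correlation). Their mean level was higher in DMSO S2_715 (0.374 on the log2 scale) than in any KU60019 library (0.297 to 0.362), against -0.193 and -0.181 in the other DMSO libraries. The rank correlation of level with length was -0.13 in S2_715 and 0.38 and 0.42 in those. The secretory phenotype list was called higher with members going both ways: 14 of 36 rose and 6 fell (15 and 6 within the list, adjusted p = 0.0394, p = 0.467 at estimated correlation). The collagenase gene Mmp13 rose (4.76 ± 0.63) and Igfbp4 fell (-2.96 ± 0.39). For mitochondrially encoded RNAs, 6 of 13 rose and 0 fell (7 and 0 within the list, adjusted p = 0.00331, p = 0.336 at estimated correlation). With each library's gene length trend removed, their adjusted p was 0.0541.

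Markers of other cell types moved in the same comparison. Of the endothelial markers, 9 of 12 fell and 0 rose (10 and 0 within the list, adjusted p = 6.01e-05, p = 0.161 at estimated correlation). Pecam1 dropped by 3.79 ± 0.51. Of the macrophage markers, 7 of 11 fell and 1 rose (7 and 1 within the list, adjusted p = 0.00310, p = 0.284 at estimated correlation). The complement gene C1qa had 1 count after KU60019 against 127 in DMSO (ratio 138, counting interval 24.4 to 5508), while Cd68, also a lysosomal gene, rose (2.10 ± 0.18). The other lists were not called. Of the mitosis list 0 of 25 rose and 2 fell (0 and 0 within the list, adjusted p = 0.352), of DNA damage response genes 1 of 26 rose and 5 fell (1 and 5 within the list, adjusted p = 0.404) and of senescence regulators 2 of 14 rose and 4 fell (2 and 5 within the list, adjusted p = 0.188). For oxidative stress response 5 of 22 rose and 3 fell (5 and 3 within the list, adjusted p = 0.198), and for aryl hydrocarbon receptor targets 1 of 6 rose and 2 fell (1 and 3 within the list, adjusted p = 0.352). For endoplasmic reticulum stress 5 of 17 rose and 3 fell (5 and 4 within the list, adjusted p = 0.848), and for cholesterol synthesis 4 of 27 rose and 1 fell (2 and 0 within the list, adjusted p = 0.106). Of epithelial markers 2 of 7 rose and 1 fell (2 and 1 within the list, adjusted p = 0.274), of mesothelial 1 of 7 rose and 1 fell (1 and 1 within the list, adjusted p = 0.783) and of pericyte 1 of 7 rose and 2 fell (1 and 3 within the list, adjusted p = 0.177). Of adipocyte markers 0 of 4 rose and 1 fell (0 and 1 within the list, adjusted p = 0.211), and of chondrocyte 0 of 6 rose and 0 fell (0 and 0 within the list, adjusted p = 0.880). For the endoplasmic reticulum stress and mesothelial lists the median lay below 0 and the test above it. Atm lost its call without DMSO S1_705 (adjusted p = 0.0839) or S3_716 (0.122) or KU60019 S5_715 (0.0886) or S6_716 (0.0507). Lmnb1 gained one without DMSO S2_715 (0.0451). Without DMSO S1_705, 3639 genes changed.

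After 35 d of KU60019, fibroblasts again had higher p53 target and interferon response genes than after 35 d of DMSO, contractile genes were lower, and several markers of Schwann cells were higher. None of these list calls held with an estimated correlation. Cdkn1a rose from 240.1 ± 15.9 to 402 ± 24.4 CPM (log2 fold change 0.74 ± 0.18, adjusted p = 0.00501) and Mdm2 by 0.38 ± 0.13 (adjusted p = 0.0396). Lmnb1 fell (log2 fold change -1.12 ± 0.18, adjusted p = 1.27e-04). Atm (-0.80 ± 0.42, adjusted p = 0.191), Cdkn2a (0.37 ± 0.31, adjusted p = 0.444), Mki67 (-0.48 ± 0.24, adjusted p = 0.173) and Il6 (-1.01 ± 0.62, adjusted p = 0.274) did not pass. In total, 3381 of 18684 genes changed, 1812 upward and 1569 downward, and among them 1175 rose and 361 fell at least 2-fold, while on TPM 660 rose and 4267 fell.

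Stmn2, a microtubule regulator of neurons (chromosome 3, 8509360 to 8561606, plus strand), rose from 0.0378 ± 0.0381 to 13 ± 4.89 CPM (log2 fold change 8.08 ± 0.88, adjusted p = 1.54e-06). Among the other largest rises, Sox10, the neural crest and Schwann cell transcription factor, reached 7.69 ± 6.93 CPM from 0.141 ± 0.134 (5.53 ± 1.19), and the neurotrophin receptor gene Ngfr rose by 5.14 ± 1.19. Esm1, which encodes the proteoglycan endocan (6.41 ± 0.51), the chemokine gene Ccl8 (5.31 ± 0.57) and Penk, the enkephalin precursor (5.17 ± 0.51), complete the 6. The largest falls were Adamtsl3 (chromosome 7, 82335694 to 82614450, plus strand, log2 fold change -3.89 ± 0.43, adjusted p = 2.11e-06) and Clca3a1 (-3.05 ± 0.65). The WNT modulator Sfrp2 (-3.04 ± 0.36), the laminin gene Lama1 (-2.94 ± 0.30), Sparcl1 (-2.80 ± 0.60) and the natriuretic peptide gene Nppc (-2.76 ± 0.47) followed.

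Of the p53 targets, 10 of 29 rose and 0 fell (12 and 0 within the list, adjusted p = 6.07e-04, p = 0.0724 at estimated correlation). Examples were Perp (4.17 ± 0.33) and Pmaip1 (2.91 ± 0.32). Of the interferon response genes, 19 of 39 rose and 0 fell (22 and 0 within the list, adjusted p = 7.48e-09, p = 0.466 at estimated correlation). Examples were Bst2, which tethers virions (2.0 ± 0.37), and the transcription factor Irf7 (2.07 ± 0.44). Contractile genes were called lower: 11 of 15 fell and 0 rose (11 and 0 within the list, adjusted p = 8.15e-09, p = 0.150 at estimated correlation). Examples were Myh11, smooth muscle myosin (-2.25 ± 0.30), and Cnn1, calponin (-2.21 ± 0.38). Extracellular matrix genes were also lower: 14 of 29 fell and 3 rose (15 and 3 within the list, adjusted p = 7.42e-08, p = 0.150 at estimated correlation). Col1a1 stood at -2.43 ± 0.26 and Col1a2 at -1.76 ± 0.16. Lysosome genes were called higher: 7 of 30 rose and 1 fell (10 and 1 within the list, adjusted p = 0.0185, p = 0.380 at estimated correlation). The immediate early list was called lower although no member passed: 0 of 15 fell and 0 rose (0 and 0 within the list, adjusted p = 0.0194, p = 0.622 at estimated correlation), median -0.72. The kinase inhibitor gene Cdkn2b (0.77 ± 0.16) and Cd68 (2.30 ± 0.18) rose, and the kinase inhibitor gene Cdkn1b (-0.86 ± 0.12) and Igfbp5 (-1.62 ± 0.29) fell.

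Mitochondrially encoded RNAs were called higher: 11 of 13 rose and 0 fell (11 and 0 within the list, adjusted p = 1.18e-11, p = 0.0724 at estimated correlation). Examples were mt-Co1 at 1.97 ± 0.26 and mt-Atp6 at 1.86 ± 0.22. These RNAs took 5.08 to 6.61% of all counts in the 3 KU60019 libraries and 1.61 to 1.73% in the 3 DMSO libraries. Epithelial markers were called higher: 3 of 7 rose and 0 fell (3 and 0 within the list, adjusted p = 0.0185, p = 0.150 at estimated correlation). Endothelial markers, of which 5 of 12 rose and 0 fell (5 and 1 within the list, adjusted p = 0.320), and the other 16 lists were not called (adjusted p from 0.0634 to 0.810). For endoplasmic reticulum stress and adipocyte markers the median and mean had opposite signs. Mdm2 lost its call without any 1 of the 6 libraries: DMSO S13_705 (adjusted p = 0.0913), S14_715 (0.0817) and S15_716 (0.0694), KU60019 S16_705 (0.10), S17_715 (0.114) and S18_716 (0.0631). On the deposited TPM neither Mdm2 (0.02, adjusted p = 0.935) nor Cdkn1a (0.39, adjusted p = 0.0791) passed. The number of genes changed was 2023 without DMSO S14_715, 1932 without DMSO S15_716 and 2221 without KU60019 S18_716.

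**Figure D2:**
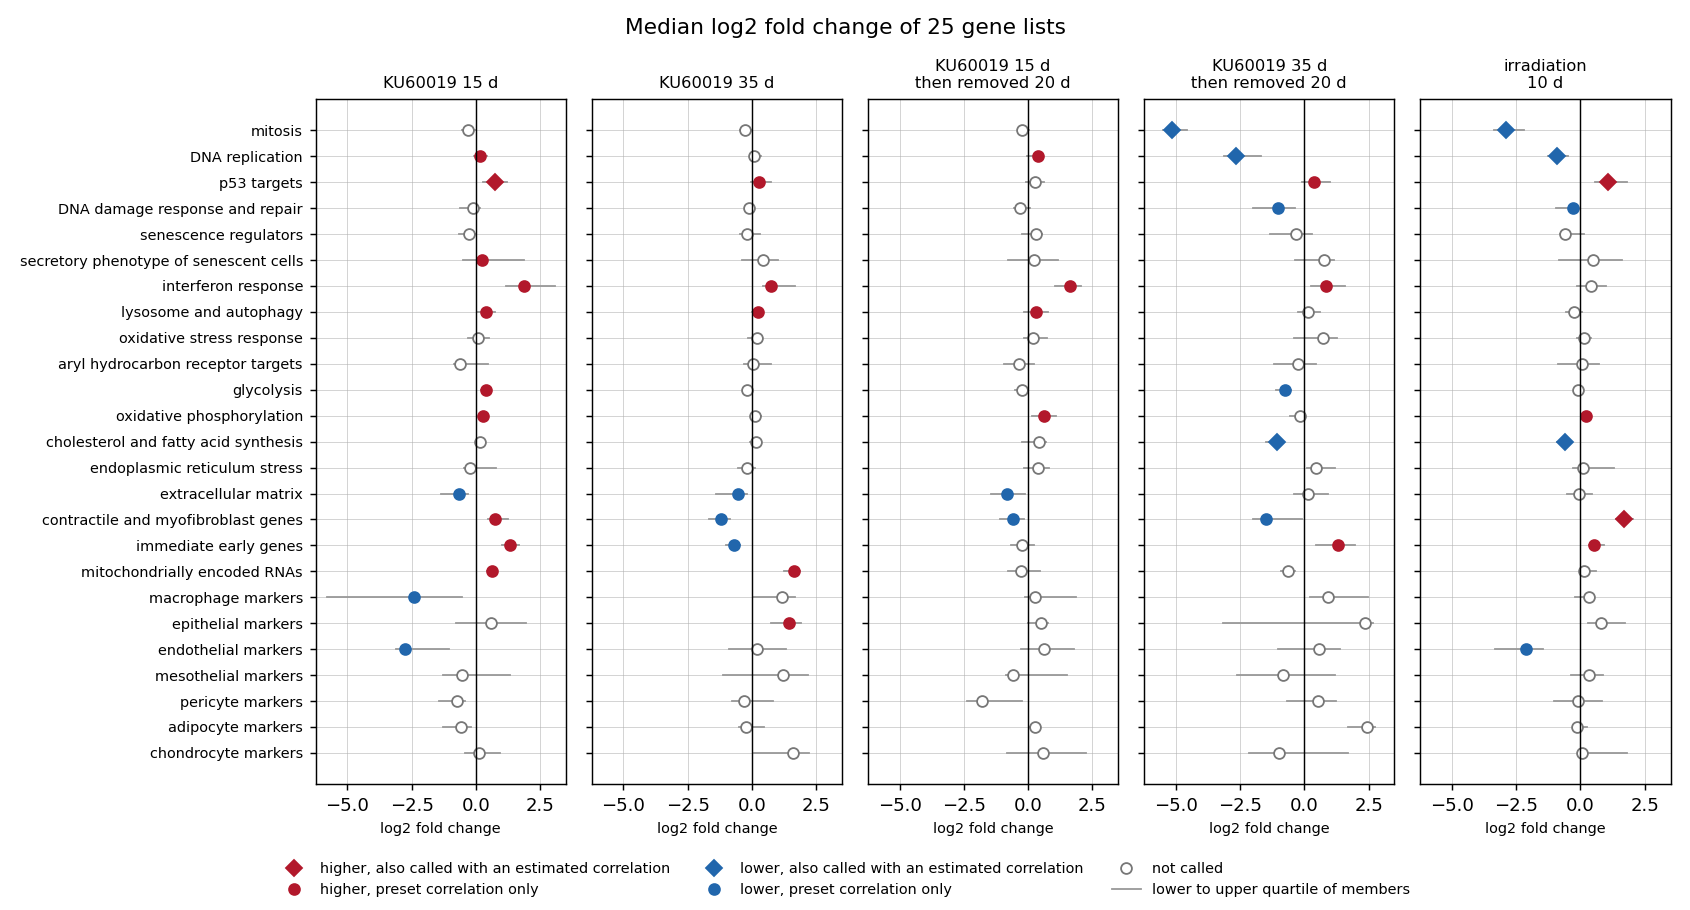
Median log2 fold change of the measured members of each of the 25 gene lists in the 5 main comparisons, with bars from the lower to the upper quartile and diamonds for lists also called with an estimated correlation. Interferon response genes had medians of 1.86 and 0.75 after 15 and 35 d of KU60019, and mitosis genes of -5.16 after 35 d plus removal and -2.89 after irradiation.

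The KU60019 effect at 35 d was set against that at 15 d by a test of the difference itself. Contractile and immediate early genes, higher at 15 d, were relatively lower at 35 d, and endothelial and macrophage markers relatively higher. The contractile and endothelial differences alone held with an estimated correlation. All but the contractile one lay largely in the DMSO cells, where from 15 to 35 d the list medians were 2.38 (immediate early), -3.32 (endothelial) and -2.90 (macrophage). In KU60019 cells the mean log2 level of endothelial markers, set to DMSO 15 d, was -2.25 to -1.77 at 15 d and -3.00 to -2.77 at 35 d, and that of immediate early genes 0.974 to 1.51 and 1.40 to 2.34. The difference was past the threshold for 2184 genes, 1329 upward and 855 downward (630 and 840 on TPM). Large positive values were those of Stmn2 (7.97 ± 1.08), the B cell chemokine gene Cxcl13 (6.22 ± 0.99), Sfrp4 (5.44 ± 0.83) and Wfdc21 (5.42 ± 1.30). The most negative were those of the cytokine gene Il11 (-4.97 ± 0.46), skeletal actin Acta1 (-5.07 ± 0.93), Asb2 (-5.14 ± 0.59), cholecystokinin Cck (-4.49 ± 0.64) and Akr1c18 (-4.16 ± 0.90). In the panel Mdm2 alone passed (log2 fold change -0.55 ± 0.18, adjusted p = 0.0483), and Lmnb1 gained a call without DMSO 15 d S3_716 (-0.84, adjusted p = 0.0340). The Mdm2 call was lost without any 1 of 10 of the 12 libraries: DMSO 15 d S2_715 (adjusted p = 0.111), KU60019 15 d S4_705 (0.0813), S5_715 (0.0986) and S6_716 (0.0860). The others were DMSO 35 d S13_705 (0.0561), S14_715 (0.0943) and S15_716 (0.109), and KU60019 35 d S16_705 (0.0741), S17_715 (0.0700) and S18_716 (0.109).

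Of the contractile genes, 12 of 15 fell and 0 rose (14 and 0 within the list, adjusted p = 4.32e-16, p = 0.0433 at estimated correlation) in this difference. Among endothelial markers 6 of 12 rose and 0 fell (9 and 0 within the list, adjusted p = 6.16e-07, p = 0.0433 at estimated correlation). Among macrophage markers 4 of 11 rose and 0 fell (5 and 0 within the list, adjusted p = 4.47e-06, p = 0.101 at estimated correlation). Lower values were called in 4 more lists. Among immediate early genes 9 of 15 fell and 0 rose (14 and 0 within the list, adjusted p = 1.41e-10, p = 0.107 at estimated correlation). Among interferon response genes 10 of 39 fell and 0 rose (16 and 1 within the list, adjusted p = 2.38e-08, p = 0.517 at estimated correlation). Among p53 targets 5 of 29 fell and 1 rose (8 and 2 within the list, adjusted p = 0.0433, p = 0.216 at estimated correlation). Among glycolysis genes 2 of 16 fell and 0 rose (7 and 0 within the list, adjusted p = 2.39e-04, p = 0.101 at estimated correlation). Higher values were called for mitochondrially encoded RNAs, where 4 of 13 rose and 0 fell (7 and 0 within the list, adjusted p = 7.48e-05, p = 0.216 at estimated correlation). The other 17 lists were not called (adjusted p from 0.0977 to 0.953), with signs of median, mean and test at odds for oxidative stress response and cholesterol synthesis. Without KU60019 15 d S5_715 the count was 1409. The block on replicate number ended the Mdm2 call (adjusted p = 0.0608).

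When KU60019 was taken away after 15 d and the cells were harvested 20 d later, interferon response genes were still higher than in cells taken off DMSO. Matrix and contractile genes were lower, though none of the 6 lists called here held with an estimated correlation, and Cdkn1a and Mdm2 no longer passed. Cdkn1a stood at 372 ± 109 against 288 ± 21.8 CPM (0.37 ± 0.18, adjusted p = 0.0847) and Mdm2 at 0.27 ± 0.13, adjusted p = 0.0807. Cdkn2a rose (log2 fold change 1.66 ± 0.32, adjusted p = 4.56e-04) and Atm fell (log2 fold change -2.21 ± 0.45, adjusted p = 6.77e-04). Mki67 was just past the threshold upward (log2 fold change 0.57 ± 0.24, adjusted p = 0.0490) and Il6 downward (log2 fold change -1.73 ± 0.63, adjusted p = 0.0290). Lmnb1 did not pass (-0.16 ± 0.17, adjusted p = 0.458). Altogether 9096 of 18684 genes changed, 4615 upward and 4481 downward, and among them 2356 rose and 2155 fell at least 2-fold. Scaled by library size alone 3761 rose and 4950 fell, and on TPM 1616 and 8360.

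The lectin gene Chodl rose the most (chromosome 16, 78930948 to 78951733, plus strand, 0.245 ± 0.0996 to 14.6 ± 8.02 CPM, log2 fold change 5.90 ± 0.60, adjusted p = 3.52e-06). It was followed by the lipocalin gene Apod (5.69 ± 0.98), the imprinted gene Dlk1, an inhibitor of adipocyte differentiation (5.64 ± 0.75), Penk (5.52 ± 0.52), the adrenoceptor gene Adra2a (5.17 ± 0.93) and the neurturin receptor gene Gfra2 (5.11 ± 0.67). Vcl, the focal adhesion protein vinculin (chromosome 14, 20929398 to 21033676, plus strand), fell the most, from 194 ± 34.1 to 6.16 ± 3.83 CPM (log2 fold change -4.96 ± 0.88, adjusted p = 2.92e-04). Zfp445 (-4.41 ± 0.81), the diacylglycerol kinase gene Dgkq (-4.37 ± 0.67), the protocadherin gene Pcdhgc5 (-4.30 ± 0.74) and Adamts12 (-4.28 ± 0.58) fell as well.

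Of the interferon response genes, 34 of 39 rose and 0 fell (35 and 0 within the list, adjusted p = 7.41e-13, p = 0.504 at estimated correlation). Bst2 stood at 3.06 ± 0.38. Oxidative phosphorylation genes were called higher: 21 of 32 rose and 1 fell (21 and 2 within the list, adjusted p = 3.91e-05, p = 0.547 at estimated correlation). Examples were Ndufs8 (1.19 ± 0.20) and Cox6c (1.73 ± 0.30). DNA replication genes were called higher: 11 of 29 rose and 1 fell (10 and 1 within the list, adjusted p = 0.0478, p = 0.552 at estimated correlation). Lysosome genes also were: 13 of 30 rose and 4 fell (14 and 4 within the list, adjusted p = 0.0468, p = 0.547 at estimated correlation). For extracellular matrix genes, 16 of 29 fell and 1 rose (16 and 1 within the list, adjusted p = 2.23e-05, p = 0.504 at estimated correlation). Examples were Col4a1 (-1.82 ± 0.21) and Col1a1 (-1.45 ± 0.25). For contractile genes, 7 of 15 fell and 0 rose (7 and 0 within the list, adjusted p = 0.0265, p = 0.552 at estimated correlation). Examples were Myh11 (-2.51 ± 0.31) and the myosin kinase gene Mylk (-1.56 ± 0.24). The short genes of oxidative phosphorylation and the long genes of the matrix moved beside a trend with gene length, and both calls held with it removed (adjusted p = 0.00355 and 1.06e-04). The rank correlation of level with length was 0.33 to 0.37 in the 3 DMSO libraries and -0.23 to -0.09 in the 3 KU60019 libraries, and that of the fold change -0.25 across genes.

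Lists not called included p53 targets, where 9 of 29 rose and 2 fell (9 and 1 within the list, adjusted p = 0.0522, and 0.0117 with the length trend removed). Of the senescence regulators 5 of 14 rose and 2 fell (5 and 3 within the list, adjusted p = 0.219). Of the pericyte markers 1 of 7 rose and 4 fell (1 and 4 within the list, adjusted p = 0.0675, and 0.0323 with the length trend removed). The apoptosis gene Bax (1.55 ± 0.28) and the kinase inhibitors Cdkn2b (1.33 ± 0.16) and Cdkn1c (1.83 ± 0.29) were higher, and the pericyte markers Kcnj8 (-2.75 ± 0.40) and Mcam (-1.99 ± 0.36) lower. Mitosis genes as a list were not called either, beside the rise of Mki67: 2 of 25 rose and 2 fell (1 and 2 within the list, adjusted p = 0.588). The 19 lists not called had adjusted p from 0.0522 to 0.977, and the signs of median, mean and test were at odds for the secretory phenotype, aryl hydrocarbon receptor targets and mitochondrially encoded RNAs. Scaling by library size alone shifted the median of all genes by -0.12. Mki67 lost its call without DMSO S7_705 (adjusted p = 0.0639), S8_715 (0.113) or S9_716 (0.122) or KU60019 S11_715 (0.150) or S12_716 (0.0906). Il6 lost it without DMSO S7_705 (0.0635) or S8_715 (0.0758) or KU60019 S11_715 (0.123) or S12_716 (0.10). Without KU60019 S10_705, Cdkn1a (adjusted p = 0.0164) and Mdm2 (0.0433) passed as higher.

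The KU60019 effect after removal differed from that before it, at 15 d, for 4751 genes, 2624 upward and 2127 downward (1125 and 2251 on TPM). The effect was smaller for Cdkn1a (difference -1.10 ± 0.25, adjusted p = 0.00329) and Mdm2 (-0.66 ± 0.18). Cdkn2a (1.79 ± 0.44) and Mki67 (log2 fold change 1.01 ± 0.33, adjusted p = 0.0294) were relatively higher. The largest positive differences were Chodl (9.79 ± 0.86), the tetranectin gene Clec3b (9.14 ± 0.83), Cxcl13 (8.83 ± 0.99), Ldb2 (8.43 ± 1.30) and Wfdc21 (8.42 ± 1.34). S100a8 (-6.78 ± 0.58), Il11 (-6.66 ± 0.48), the mast cell protease gene Mcpt8 (-6.34 ± 0.77) and the granzyme genes Gzmd (-6.19 ± 1.09) and Gzme (-6.18 ± 0.72), near copies that may share reads, went down. Among p53 targets 10 of 29 fell and 2 rose (10 and 3 within the list, adjusted p = 0.0180, p = 0.160 at estimated correlation). Of contractile genes 10 of 15 fell and 0 rose (10 and 0 within the list, adjusted p = 1.07e-06). Of immediate early genes 9 of 15 fell and 0 rose (11 and 0 within the list, adjusted p = 8.57e-05). Of glycolysis genes 7 of 16 fell and 0 rose (8 and 0 within the list, adjusted p = 0.00116). At estimated correlation p was 0.160, 0.426 and 0.160 in turn. Higher values were called in 3 lists. Of the endothelial markers, 9 of 12 rose and 0 fell (10 and 0 within the list, adjusted p = 2.43e-05, p = 0.160 at estimated correlation). Of the senescence regulators, 6 of 14 rose and 2 fell (7 and 3 within the list, adjusted p = 0.0444, p = 0.160 at estimated correlation). Of the macrophage markers, 2 of 11 rose and 1 fell (4 and 1 within the list, adjusted p = 0.0111, p = 0.426 at estimated correlation). The other 18 lists were not called (adjusted p from 0.0505 to 0.982). Signs were at odds for mitosis, DNA replication, oxidative stress response, cholesterol synthesis and epithelial, mesothelial and pericyte markers. Mki67 lost its call without DMSO 15 d S2_715 (adjusted p = 0.0545) or S3_716 (0.0758), KU60019 15 d S4_705 (0.0703), DMSO removed S8_715 (0.0603) or S9_716 (0.0610) or KU60019 removed S11_715 (0.0701). Il6 (-1.38 ± 0.88, adjusted p = 0.249) gained one without KU60019 removed S10_705 (0.0296).

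In the arms more genes changed in KU60019 cells. The list medians of endothelial (-3.12), macrophage (-2.92), immediate early (2.02) and contractile genes (1.08) moved more in DMSO than in KU60019 cells (-0.23, -0.31, 0.77 and -0.16). The mean log2 level of p53 targets, set to DMSO 15 d, was 0.38 to 0.52 in DMSO removed. It was 0.79 to 0.85 in KU60019 15 d and 0.73 to 0.88 in KU60019 removed. Between 15 d and removal 7527 genes (3973 up, 3554 down) changed in KU60019 and 1312 (706 up, 606 down) in DMSO. Scaled by library size alone these became 2711 and 4967 (shift of -0.21) and 433 and 843 (-0.12), and on TPM 1659 and 5169, and 387 and 397. Without 1 library the DMSO count was 786 (DMSO 15 d S2_715) and 865, 777 and 754 (removed S7_705, S8_715 and S9_716).

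When KU60019 was taken away after 35 d and the cells were harvested 20 d later, mitosis and DNA replication genes were far lower than in cells taken off DMSO. Mki67 stood at 3.69 ± 0.990 CPM against 392 ± 77.2 (log2 fold change -6.74 ± 0.30, adjusted p = 1.99e-13), and Lmnb1 fell as well (-3.59 ± 0.19, adjusted p = 2.58e-12). Cdkn1a (0.62 ± 0.18, adjusted p = 0.00612) and Il6 (3.30 ± 0.69, adjusted p = 4.07e-04) were higher. In the cells taken off DMSO, Il6 was lower than in DMSO 15 d. Atm fell (-1.14 ± 0.44, adjusted p = 0.0367). Cdkn2a (0.38 ± 0.31, adjusted p = 0.324) and Mdm2 (0.13 ± 0.13, adjusted p = 0.391) did not pass. Of 18684 genes, 9130 changed, 4554 upward and 4576 downward, and among them 2820 rose and 2301 fell at least 2-fold. Scaled by library size alone, 6355 rose and 2669 fell, a shift of 0.29 in the median of all genes, on TPM 5952 and 1751, and TMM gave the DMSO library S19_705 of this pair a factor of 0.694.

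Of the mitosis genes, 25 of 25 fell and 0 rose (25 and 0 within the list, adjusted p = 1.61e-27, p = 0.0336 at estimated correlation), with a median of -5.16. The spindle genes Ska1 (-6.49 ± 0.43) and Kif2c (-6.48 ± 0.32), Pclaf, a PCNA-binding factor (-5.98 ± 0.35), Mxd3 (-5.98 ± 0.35) and cyclin B1 gene Ccnb1 (-5.95 ± 0.31) stood with Mki67 as the largest falls. Of the DNA replication genes, 28 of 29 fell and 0 rose (29 and 0 within the list, adjusted p = 3.19e-22, p = 0.00497 at estimated correlation). Examples were the helicase subunit Mcm6 (-3.77 ± 0.14) and thymidine kinase Tk1 (-5.23 ± 0.24). Repair and damage response genes were called lower: 19 of 26 fell and 3 rose (19 and 3 within the list, adjusted p = 7.46e-05, p = 0.215 at estimated correlation). Brca1, of homologous recombination, stood at -3.35 ± 0.26. Of the cholesterol and fatty acid synthesis genes, 25 of 27 fell and 0 rose (25 and 0 within the list, adjusted p = 6.01e-11, p = 0.0143 at estimated correlation). Examples were Cyp51 (-2.28 ± 0.14) and Sqle (-1.81 ± 0.15), both sterol synthesis enzymes. Of the glycolysis genes, 13 of 16 fell and 1 rose (14 and 1 within the list, adjusted p = 2.22e-04, p = 0.0883 at estimated correlation). Examples were Pkm (-1.85 ± 0.25) and Eno1 (-1.51 ± 0.18). Contractile genes were lower too: 9 of 15 fell and 2 rose (10 and 2 within the list, adjusted p = 0.00441, p = 0.464 at estimated correlation). Examples were Acta2 (-2.23 ± 0.26) and Cnn1 (-3.53 ± 0.40).

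Adamtsl2, which binds microfibrils (chromosome 2, 27079379 to 27108981, plus strand), rose from 0.149 ± 0.0913 to 39.7 ± 6.24 CPM (log2 fold change 8.07 ± 1.04, adjusted p = 1.44e-06). Next were Gprasp2 (7.25 ± 0.39), the immunoglobulin gene Ighm (6.62 ± 0.56), Wfdc17 (6.47 ± 1.42) and the glutathione transferase gene Gsta3 (6.36 ± 0.52). Tnfsf18, a TNF family ligand gene, had 1 count in DMSO and 933 after KU60019 (ratio 657, counting interval 118 to 25985). Of the p53 targets, 13 of 29 rose and 3 fell (13 and 3 within the list, adjusted p = 0.0310, p = 0.215 at estimated correlation). Examples were the stress cytokine Gdf15 (4.15 ± 0.34) and the death receptor Fas (1.87 ± 0.24). With the length trend removed their adjusted p was 0.0570. Of the interferon response genes, 21 of 39 rose and 0 fell (21 and 0 within the list, adjusted p = 0.00303, p = 0.602 at estimated correlation). Of the immediate early genes, 8 of 15 rose and 0 fell (9 and 0 within the list, adjusted p = 0.0447, p = 0.602 at estimated correlation). The adjusted p of the list was 0.0502 with the replicate number as a block, under which adipocyte markers were called (0.0307).

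Matrix genes were not called as a list: 11 of 29 rose and 7 fell (11 and 8 within the list, adjusted p = 0.452). The proteoglycan gene Dcn (3.92 ± 0.46) and elastin Eln (4.16 ± 0.53) were higher. Of the macrophage markers 2 of 11 rose and 0 fell (2 and 0 within the list, adjusted p = 0.155), and of the epithelial 3 of 7 rose and 3 fell (4 and 3 within the list, adjusted p = 0.592), neither called. Cd68 was higher (2.97 ± 0.19) and the keratin gene Krt19 lower (-3.53 ± 0.41). The 16 lists not called had adjusted p from 0.0501 to 0.929, with the test of mesothelial markers opposite in sign to their median. The DMSO libraries S19_705 and S20_715 had 2.91 and 0.431% of counts in rRNA genes, against 0.0510% in S21_716. Without libraries above 0.4%, which leaves S21_716 alone in that group, 5596 genes changed and Il6 (2.50, adjusted p = 0.0762) and Atm (-0.45, adjusted p = 0.643) did not pass. With only these groups in the fit 5487 changed. Atm lost its call without DMSO S19_705 (adjusted p = 0.190) or S20_715 (0.0548) or KU60019 S22_705 (0.103), S23_715 (0.0604) or S24_716 (0.0754). Cdkn1a lost it with the length trend removed (0.0523).

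Set against the effect at 35 d by a test of the difference, the effect after removal differed for 6060 genes, 2952 upward and 3108 downward. These became 4504 and 1763 scaled by library size alone (shift of 0.32), 7723 and 808 on TPM and 2966 in all without the rRNA-rich libraries. Mki67 (log2 fold change -6.26 ± 0.36, adjusted p = 5.86e-11) and Lmnb1 (-2.46 ± 0.25) were relatively lower and Il6 relatively higher (log2 fold change 4.31 ± 0.92, adjusted p = 0.00123). Adamtsl2 (8.22 ± 1.24), Cxcl13 (7.61 ± 1.99), Palmd (6.60 ± 0.62) and the bone morphogenetic protein pathway genes Bmp3 (6.42 ± 0.44) and Chrdl2 (6.08 ± 0.67) had the largest positive values. Prl2c3 (-7.50 ± 1.19), Prl2c2 (-7.45 ± 1.15), Nrgn (-7.01 ± 1.25), Stmn2 (-6.59 ± 1.07) and Ska1 (-6.54 ± 0.55) had the most negative. Of the mitosis genes, 25 of 25 fell and 0 rose (25 and 0 within the list, adjusted p = 4.43e-33, p = 0.0165 at estimated correlation). Of the DNA replication genes, 28 of 29 fell and 0 rose (29 and 0 within the list, adjusted p = 1.13e-27, p = 0.00149 at estimated correlation). Of the cholesterol synthesis genes, 23 of 27 fell and 0 rose (24 and 0 within the list, adjusted p = 5.93e-14, p = 0.00446 at estimated correlation). Lower values were called in 4 further lists. Of the repair genes, 14 of 26 fell and 3 rose (14 and 3 within the list, adjusted p = 1.81e-04, p = 0.276 at estimated correlation). Of the glycolysis genes, 8 of 16 fell and 1 rose (9 and 1 within the list, adjusted p = 0.00190, p = 0.175 at estimated correlation). Of the oxidative phosphorylation genes, 11 of 32 fell and 0 rose (11 and 0 within the list, adjusted p = 0.00971, p = 0.512 at estimated correlation). Of the mitochondrially encoded RNAs, 12 of 13 fell and 0 rose (12 and 0 within the list, adjusted p = 1.5e-07, p = 0.106 at estimated correlation). Higher values were called in 3. Among matrix genes 17 of 29 rose and 1 fell (18 and 1 within the list, adjusted p = 3.24e-06, p = 0.205 at estimated correlation). Among immediate early genes 8 of 15 rose and 0 fell (8 and 0 within the list, adjusted p = 8.38e-04, p = 0.430 at estimated correlation). Among endoplasmic reticulum stress genes 6 of 17 rose and 0 fell (6 and 0 within the list, adjusted p = 0.00971, p = 0.510 at estimated correlation). The block added adipocyte markers (adjusted p = 0.0238). The other 15 lists were not called (adjusted p from 0.0952 to 0.980), and signs were at odds for p53 targets, lysosome, contractile and epithelial lists.

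In this pair of arms the DMSO cells moved more: 11978 genes, 5889 upward and 6089 downward, against 2352 genes, 1078 upward and 1274 downward, in KU60019. Scaled by library size alone these became 4389 and 7310 (shift of -0.25) and 1510 and 728, and on TPM 2146 and 9828, and 1077 and 405. In DMSO cells mitosis genes were higher after the further 20 d: 24 of 25 rose and 0 fell (25 and 0 within the list, adjusted p = 3.37e-16, p = 0.236 at estimated correlation). DNA replication genes were too: 28 of 29 rose and 0 fell (28 and 0 within the list, adjusted p = 5.25e-16, p = 0.0246 at estimated correlation). In KU60019 cells mitosis genes fell over the same 20 d: 21 of 25 fell and 0 rose (23 and 0 within the list, adjusted p = 3.93e-17, p = 0.116 at estimated correlation). In DMSO cells matrix genes were lower: 23 of 29 fell and 1 rose (23 and 1 within the list, adjusted p = 3.65e-06, p = 0.289 at estimated correlation). Without 1 library the KU60019 count was 659 (KU60019 35 d S16_705), 1182 (KU60019 35 d S17_715), 1075 (removed S22_705) or 629 (removed S24_716).

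DMSO groups were compared with each other to show what time in culture did without the inhibitor. From 15 to 35 d endothelial RNA was lost and immediate early RNA rose. Pecam1, an endothelial adhesion molecule, went from 11.2 ± 7.55 to 0.363 ± 0.238 CPM (log2 fold change -4.99 ± 0.56, adjusted p = 1.88e-05). Cldn5 (-5.81 ± 0.78) and Cdh5 (-4.67 ± 0.66) of endothelial junctions, the receptor gene Tie1 (-5.52 ± 0.94) and Lyve1 (-5.04 ± 1.06) fell too. Fosb (5.59 ± 0.77), Fos (4.40 ± 0.51), Egr1 (3.24 ± 0.50), Ier2 (3.19 ± 0.26) and Dusp1 (3.04 ± 0.36) rose. Of immediate early genes 11 of 15 rose and 0 fell (14 and 0 within the list, adjusted p = 2.03e-46). Of endothelial markers 10 of 12 fell and 0 rose (12 and 0 within the list, adjusted p = 1.29e-33). Of macrophage markers 6 of 11 fell and 0 rose (8 and 0 within the list, adjusted p = 3.87e-15). Of pericyte markers 2 of 7 fell and 0 rose (3 and 0 within the list, adjusted p = 0.0119). At estimated correlation p was 4.91e-04, 9.31e-06, 0.00261 and 0.0429 in turn. Cholesterol synthesis genes were called lower: 3 of 27 fell and 0 rose (11 and 0 within the list, adjusted p = 3.95e-13, p = 0.00329 at estimated correlation). The p53 targets were called higher: 4 of 29 rose and 0 fell (7 and 0 within the list, adjusted p = 1.86e-06, p = 0.00362 at estimated correlation). No panel gene passed, Mki67 being at -0.89 ± 0.24, adjusted p = 0.0611.

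Further lists were called with few or no members passing. Lower values were called in 4 of them. In the mitosis list 0 rose and 2 fell (0 and 17 within the list, adjusted p = 8.19e-15, p = 0.0844 at estimated correlation). In the DNA replication, interferon response and lysosome lists 0 rose and 0 fell, also within the list. Their adjusted p was 3.02e-06, 0.00557 and 0.00823, with p = 0.0844, 0.643 and 0.207 at estimated correlation. Higher values were called in 5. In the secretory phenotype list 3 rose and 2 fell (5 and 3 within the list, adjusted p = 0.00614, p = 0.459 at estimated correlation). In the glycolysis and endoplasmic reticulum stress lists 0 rose and 0 fell, also within the list. Their adjusted p was 0.00179 and 0.0218, with p = 0.0844 and 0.524 at estimated correlation. In the matrix list 1 rose and 0 fell (8 and 0 within the list, adjusted p = 1.33e-11, p = 0.0353 at estimated correlation). In the contractile list 1 rose and 0 fell (2 and 0 within the list, adjusted p = 3.05e-07, p = 0.0844 at estimated correlation). The whole comparison held 292 genes, 85 upward and 207 downward, or 55 and 235 scaled by library size alone. It was 14 with only these groups in the fit, 454 with DESeq2, 141 on TPM (36 and 105) and 150, 177 and 125 without DMSO 35 d S13_705, S14_715 or S15_716. With only these groups Pecam1, Cldn5, Cdh5, Tie1, Lyve1, Fos and Egr1 did not pass (adjusted p from 0.0575 to 0.264). Lyve1 lost its call without DMSO 15 d S1_705 (adjusted p = 0.200) or DMSO 35 d S13_705 (0.0521), S14_715 (0.0773) or S15_716 (0.0991). Mki67 gained one, as lower, without DMSO 15 d S1_705 (0.0206) or DMSO 35 d S14_715 (0.0405) and with the replicate block (0.0443). The other 10 lists were not called (adjusted p from 0.0515 to 0.726), and signs were at odds for oxidative stress response, aryl hydrocarbon receptor targets and mesothelial and chondrocyte markers.

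Cells carried in DMSO for 35 d and then without it for 20 d had high RNA of mitosis and DNA replication genes, the latter call alone holding with an estimated correlation. Mki67 reached 392 ± 77.2 CPM from 27.6 ± 8.30 at 15 d (log2 fold change 3.82 ± 0.26, adjusted p = 1.65e-10). Lmnb1 (1.76 ± 0.18), Cdkn1a (1.61 ± 0.18), Cdkn2a (1.42 ± 0.32) and Mdm2 (0.86 ± 0.13) rose, Il6 fell (-4.12 ± 0.71) and Atm did not pass (-0.62 ± 0.42, adjusted p = 0.200). Prl2c3 (7.83 ± 0.93), Prl2c2 (7.60 ± 0.90), Akr1c18 (7.60 ± 0.60), Crct1 (7.20 ± 0.63) and the interleukin 33 receptor gene Il1rl1 (7.13 ± 0.97) had the largest rises.

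Wfdc21, Shisa3 and Tie1 had no count in this group and were at least 153-, 129- and 112-fold lower than at 15 d, against a floor of 3 counts over the group. Ngfr had 2 counts against 1374 (ratio 405, counting interval 112 to 3346), and Wfdc17 fell (-7.98 ± 1.38). Of the mitosis genes, 23 of 25 rose and 0 fell (23 and 0 within the list, adjusted p = 4.63e-14, p = 0.202 at estimated correlation). Of the DNA replication genes, 28 of 29 rose and 0 fell (28 and 0 within the list, adjusted p = 1.56e-14, p = 0.0345 at estimated correlation). Called higher were 7 more lists. Of oxidative phosphorylation genes 22 of 32 rose and 1 fell (22 and 2 within the list, adjusted p = 1.15e-04). Of cholesterol synthesis genes 13 of 27 rose and 3 fell (13 and 3 within the list, adjusted p = 0.0218). Of repair genes 17 of 26 rose and 4 fell (18 and 4 within the list, adjusted p = 0.00491). Of glycolysis genes 10 of 16 rose and 1 fell (10 and 1 within the list, adjusted p = 0.0119). Of contractile genes 11 of 15 rose and 2 fell (11 and 2 within the list, adjusted p = 0.00279). Of p53 targets 17 of 29 rose and 6 fell (17 and 6 within the list, adjusted p = 0.00744). At estimated correlation p was 0.356, 0.356, 0.356, 0.332, 0.356 and 0.202 in turn. Of mitochondrially encoded RNAs 10 of 13 rose and 1 fell (10 and 1 within the list, adjusted p = 0.0208, p = 0.451 at estimated correlation), and adjusted p = 0.310 with the length trend removed. Called lower were 4. Of matrix genes 16 of 29 fell and 1 rose (15 and 1 within the list, adjusted p = 0.00279). Of interferon response genes 22 of 39 fell and 1 rose (22 and 1 within the list, adjusted p = 0.00279). Of macrophage markers 7 of 11 fell and 0 rose (8 and 0 within the list, adjusted p = 0.0101). Of endothelial markers 12 of 12 fell and 0 rose (12 and 0 within the list, adjusted p = 9.67e-05). At estimated correlation p was 0.356, 0.558, 0.356 and 0.159 in turn. The comparison held 11777 genes, 5745 upward and 6032 downward, or 3964 and 7834 scaled by library size alone (shift of -0.31), 1992 and 9693 on TPM, 6728 in all with only these groups in the fit and 7105 without the rRNA-rich libraries. The other 12 lists were not called (adjusted p from 0.110 to 0.921), and Atm passed as lower without DMSO 15 d S2_715 (adjusted p = 0.0234).

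**Figure D3:**
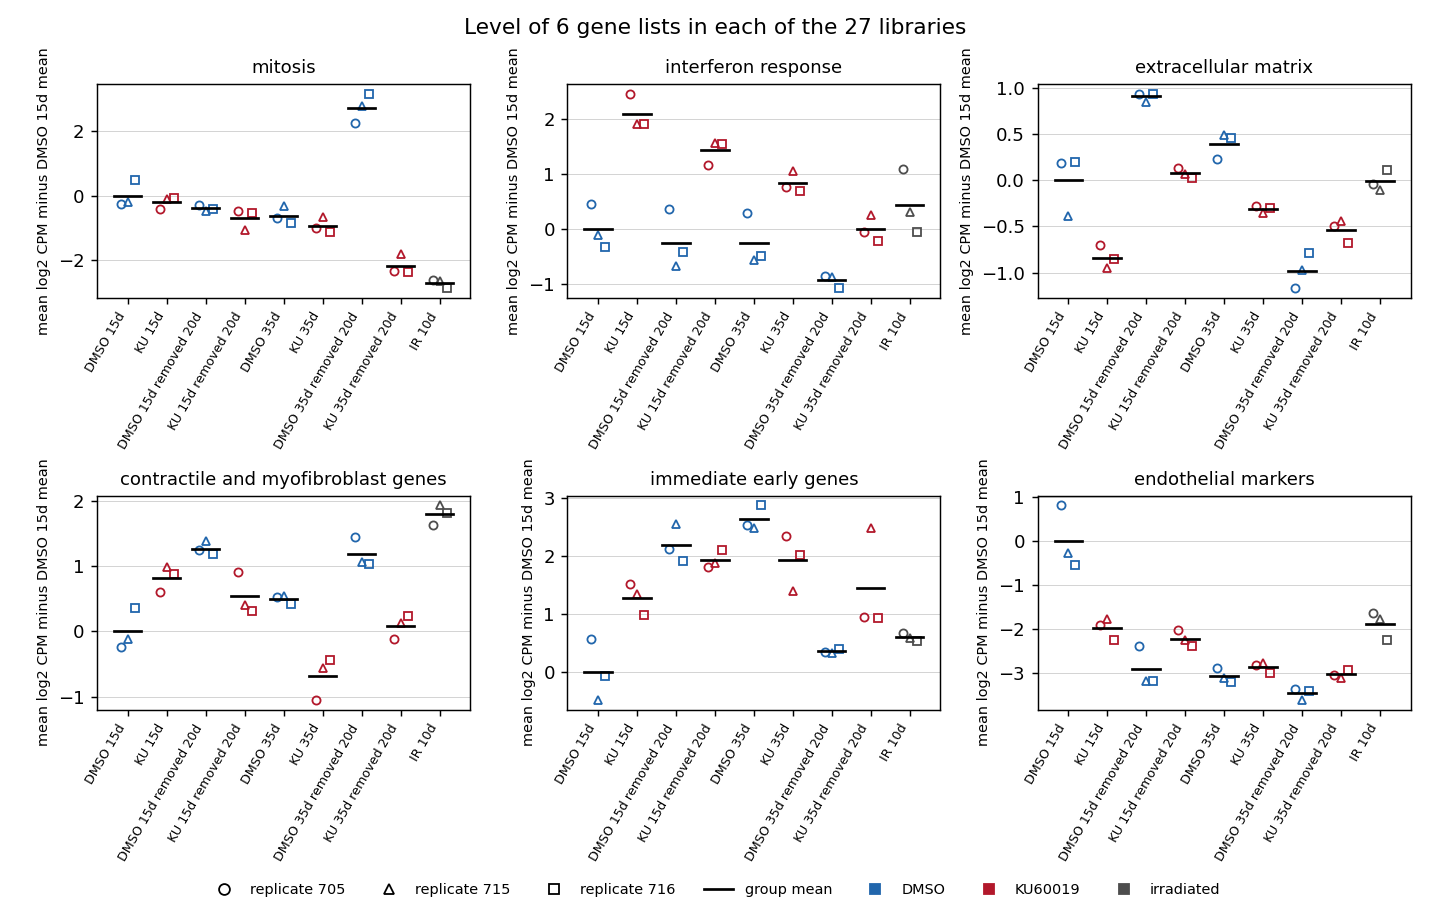
Mean log2 CPM of the measured members of 6 gene lists in each of the 27 libraries, minus the mean of the 3 DMSO 15 d libraries (points are libraries). Mitosis genes in the 3 libraries of the DMSO group of 35 d plus removal lay between 2.25 and 3.16 above that mean.

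Irradiated cells, 10 d after 10 Gy, are the labelled positive control for senescence and were compared with DMSO 15 d, as no unirradiated group without vehicle is labelled. They had far less mitosis and replication RNA, and more of p53 target and contractile genes. Cdkn1a rose from 163 ± 15.9 to 1182 ± 187 CPM (log2 fold change 2.86 ± 0.19, adjusted p = 1.53e-09) and Mdm2 by 1.19 ± 0.13. Mki67 fell to 1.01 ± 0.301 CPM (log2 fold change -4.74 ± 0.29, adjusted p = 6.7e-10), Lmnb1 dropped by 1.81 ± 0.18 and Atm fell (log2 fold change -1.59 ± 0.43, adjusted p = 0.00713). Cdkn2a (-0.77 ± 0.32, adjusted p = 0.0702) and Il6 (-0.86 ± 0.62, adjusted p = 0.309) did not pass. Altogether 5765 of 18684 genes changed, 2632 upward and 3133 downward, and among them 1180 rose and 1506 fell at least 2-fold. On TPM 1315 rose and 3201 fell.

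Of the p53 targets, 24 of 29 rose and 1 fell (27 and 1 within the list, adjusted p = 2.83e-15, p = 7.1e-05 at estimated correlation). Examples were Psrc1 (2.62 ± 0.14), Perp (3.83 ± 0.32) and Gdf15 (4.47 ± 0.34). Of the mitosis genes, 25 of 25 fell and 0 rose (25 and 0 within the list, adjusted p = 4.45e-27, p = 0.0359 at estimated correlation). Examples were Nusap1 (-3.61 ± 0.24), topoisomerase Top2a (-3.29 ± 0.25) and the hyaluronan receptor gene Hmmr (-4.80 ± 0.46). Of the DNA replication genes, 18 of 29 fell and 0 rose (20 and 0 within the list, adjusted p = 1.64e-09, p = 0.0426 at estimated correlation). Examples were Mcm6 (-1.66 ± 0.13) and Tk1 (-2.35 ± 0.22). For repair genes, 9 of 26 fell and 0 rose (9 and 0 within the list, adjusted p = 0.00965, p = 0.423 at estimated correlation). With the length trend removed the adjusted p of the list was 0.0517. Contractile genes were called higher: 14 of 15 rose and 0 fell (14 and 0 within the list, adjusted p = 1.61e-12, p = 0.0359 at estimated correlation). Examples were Ccn2 (3.39 ± 0.29), Tagln (2.23 ± 0.30) and tropomyosin Tpm1 (1.51 ± 0.16). Of the cholesterol and fatty acid synthesis genes, 17 of 27 fell and 1 rose (19 and 1 within the list, adjusted p = 7.38e-08, p = 0.0359 at estimated correlation). Examples were Insig1 (-1.44 ± 0.15) and the desaturase gene Scd1 (-1.21 ± 0.15). Called higher with few members past the threshold were oxidative phosphorylation genes, where 3 of 32 rose and 0 fell (3 and 0 within the list, adjusted p = 0.0420, p = 0.696 at estimated correlation), with adjusted p = 0.209 once the length trend was removed. So were immediate early genes, where 3 of 15 rose and 0 fell (3 and 0 within the list, adjusted p = 0.0251, p = 0.691 at estimated correlation).

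Vgf, a secreted neuropeptide precursor (chromosome 5, 137026392 to 137033351, plus strand), rose from 0.888 ± 0.0612 to 36.1 ± 14.2 CPM (log2 fold change 5.33 ± 0.33, adjusted p = 6.7e-10). Next were Crct1 (4.93 ± 0.61), the adenosine receptor gene Adora1 (4.69 ± 0.65), Prss46 (4.44 ± 0.59) and the cytochrome oxidase subunit gene Cox6a2 (4.15 ± 0.43). Clec3b (chromosome 9, 123150946 to 123157432, plus strand, log2 fold change -5.21 ± 0.63, adjusted p = 2.83e-06), the metalloreductase gene Steap4 (-5.12 ± 0.90), Sfrp2 (-5.04 ± 0.40) and the claudin gene Cldn2 (-4.75 ± 0.50) fell the most beside Hmmr and Mki67. The secretory phenotype list was not called: 14 of 36 rose and 6 fell (15 and 6 within the list, adjusted p = 0.0526). Igfbp5 fell (-2.49 ± 0.30) and Cd68 rose (1.93 ± 0.18). Of the interferon response genes, 11 of 39 rose and 0 fell (11 and 0 within the list, adjusted p = 0.0574), and of the matrix genes, 7 of 29 rose and 7 fell (8 and 8 within the list, adjusted p = 0.808), neither called. With the replicate number as a block the tests of the secretory (0.0423), interferon (0.0422) and lysosome lists (0.0488) passed. The 16 lists not called had adjusted p from 0.0526 to 0.982, with signs at odds for aryl hydrocarbon receptor targets and adipocyte markers. Endothelial markers were called lower: 10 of 12 fell and 0 rose (10 and 0 within the list, adjusted p = 2.87e-04, p = 0.0908 at estimated correlation). Against DMSO 35 d, where these markers were already low, Pecam1 turned from -2.83 ± 0.48 to 2.16 (adjusted p = 0.00518) and Cdh5 from -3.47 ± 0.62 to 1.20 (0.172). Atm lost its call without DMSO S3_716 (adjusted p = 0.0512), and Cdkn2a gained one, as lower, without irradiated S25_705 (0.00164).

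Since irradiated cells served as the senescent reference, the KU60019 effects were set beside the irradiation effect gene by gene, with different DMSO groups as controls so that none was shared. For 15 d of KU60019, with irradiation taken against DMSO 35 d, 1030 genes rose in both (319 for independent lists), 1308 fell in both (454) and 224 moved in opposite directions (763). The log2 fold changes correlated across genes, which are not independent replicates, at r = 0.44. For 35 d of KU60019, 827 genes rose in both (255 for independent lists), 827 fell in both (263) and 174 moved in opposite directions (525), at r = 0.48. With these controls the overlap after removal was smaller relative to independent lists. For the 15 d group, 665 genes rose in both (650.1 for independent lists), 1027 fell in both (751) and 935 moved in opposite directions (1405), at r = 0.24. For the 35 d group, 1149 genes rose in both (642 for independent lists), 1141 fell in both (767) and 913 moved in opposite directions (1408), at r = 0.18. With irradiation against DMSO 35 d these became r = 0.36 for the 15 d group and 0.20 for the 35 d group. Against the mean of the 4 DMSO groups they were r = 0.12, with 611 risen in both (763), and r = 0.58, with 1959 risen in both (753). That mean shares libraries with each effect, and no unchanged groups were simulated for it, so these have no baseline. With DMSO 15 d as the control of both effects, the 15 d value was r = 0.61, where unchanged groups simulated against those libraries gave a mean of 0.50 (from 0.48 to 0.52 in 10 simulations). The covariance was 0.573 against a simulated 0.0877, a difference of 0.485. The 3 control libraries cannot be split into sets of 2, so part of any excess may come from the shared controls.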

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

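Tests of the proliferative DMSO group below were chosen after its values were seen, those of random splits before their results. Each value here was picked because the KU60019 effect differed by time or between kept and removed inhibitor by a test of the difference. Removed groups were 20 d longer in culture, so the latter cannot tell removal from time. Groups of equal age (15 d plus removal, 35 d) were not compared. Between 35 and 15 d, 2184 genes differed, with Mdm2 at -0.55 and list medians of -0.26 for p53 targets, -1.06 for interferon response, -0.53 for glycolysis, -1.91 for contractile and -1.90 for immediate early genes, 1.05 for mitochondrially encoded RNAs and 2.88 for macrophage and 2.09 for endothelial markers. Between removed and kept inhibitor at 15 d, 4751 genes differed, with Cdkn1a at -1.10, Cdkn2a at 1.79, Mdm2 at -0.66 and Mki67 at 1.01. Its list medians were -0.43 for p53 targets, 0.56 for senescence regulators, -0.48 for glycolysis, -1.39 for contractile and -1.42 for immediate early genes, 3.14 for macrophage and 3.38 for endothelial markers. At 35 d, 6060 genes differed, with Mki67 at -6.26, Lmnb1 at -2.46 and Il6 at 4.31. Its list medians were -4.93 for mitosis, -2.59 for DNA replication, -0.81 for repair, -0.64 for glycolysis, -0.33 for oxidative phosphorylation, -1.38 for cholesterol synthesis, 0.74 for endoplasmic reticulum stress, 0.97 for matrix and 1.79 for immediate early genes and -2.33 for mitochondrially encoded RNAs.

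With only the 12 libraries of each difference in the fit, 100 splits into groups of the same sizes were drawn, the real one included. The 35 against 15 d difference gave 3267 genes, reached in 2 splits, the highest other with 8521. That split set both KU60019 groups against mixed DMSO libraries, so its count points to a structure of the samples. Removed against kept gave 3816 at 15 d, reached in 3 splits with the highest other at 6978, in a split that kept the KU60019 15 d libraries together, and 4852 at 35 d, reached in 1 with the highest other at 1759. The splits mix groups that KU60019 and time set apart, which widens the spread within them, so they do not test the difference of effects.

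The large negative difference of mitosis genes at 35 d rests mostly on the DMSO arm (list median 3.69, against -1.29 in the KU60019 arm), where Mki67 was 480.1, 357 and 338 CPM after the further 20 d. High rRNA in part of that group is argued against: over 3 groups, the 4 rRNA-rich libraries had at most 0.162 more mean log2 CPM of mitosis genes than the others of their group, against a rise of 3.34, a test that replaced a fit leaving 1 library. Epithelial cells stay open, as Epcam plus Cdh1 (0.0423 CPM) lay near the floor in all groups. Of 7 epithelial markers 3 rose against DMSO 35 d, Krt19 from 1.43 ± 0.260 to 40.3 ± 23.7 CPM. Loss of p53 function stays open, as p53 targets went both ways against DMSO 35 d (median 0.37, 16 rose, 8 fell). Also open, but confounded with the group and untested, is a change in the fibroblasts with long culture, such as outgrowth of dividing cells.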

How the results depend on the processing

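The fits with the length trend removed, with protein-coding genes alone and without rRNA-rich libraries, and the 4 removal arms, were chosen after the data were seen. Over all settings, 4282 values of named genes kept their side of the threshold, 90 dropped below it, 37 passed it and 5 with a call turned. For list tests these were 2701, 138, 110 and 1, and 208 counts of genes stayed within 1.5 times while 30 did not. With irradiation set against DMSO 35 d or the mean of the 4 DMSO groups, Pecam1 turned to 2.16 and 1.29 and Cdh5 to 1.20 and 0.0545. On TPM the removed against kept difference of Cdkn1a at 35 d turned to 0.73, and without DMSO 15 d S2_715 oxidative phosphorylation genes in DMSO 35 against 15 d were called the other way (adjusted p = 0.00582, and 0.00228 to 0.984 as each library was left out in turn). The cause was not tested. With only the compared groups in the fit, which pools less information on the spread, counts were 5487 for 35 d plus removal, 14 for DMSO 35 against 15 d, 6728 for DMSO 35 d plus removal against 15 d, 4375 for the KU60019 arm at 35 d and 800 for the DMSO arm at 15 d. Without rRNA-rich libraries, where S21_716 alone stands for DMSO 35 d plus removal and other groups supply the spread, they were 5596 for 35 d plus removal, 2966 for its difference, 7105 for DMSO 35 d plus removal and 7381 for the DMSO arm at 35 d. On TPM they were 141 for DMSO 35 against 15 d, 784 for the DMSO arm at 15 d and 1482 for the KU60019 arm at 35 d, which without a filter on low counts had 1325, and DESeq2 called 454 for DMSO 35 against 15 d. On TPM, 20 calls turned for 15 d plus removal, 7 for the removed against kept difference at 35 d, 411 for DMSO 35 d plus removal and 477 for the DMSO arm at 35 d. With the length trend removed, cholesterol synthesis genes were called higher at 15 d (adjusted p = 0.0113), 35 d (0.0106) and 15 d plus removal (0.00816), mitochondrially encoded RNAs lower in the removed against kept difference at 15 d (0.0205) and repair genes lower in DMSO 35 against 15 d (0.0295). It ended the calls of immediate early genes at 35 d plus removal (0.0570), p53 targets in the 35 against 15 d difference (0.0525) and oxidative phosphorylation genes in the removed against kept difference at 35 d (0.0724). Leaving out 1 library gave 3639 to 7079 (15 d), 1932 to 3586 (35 d), 6763 to 9889 (15 d plus removal), 7970 to 9857 (35 d plus removal), 4031 to 7017 (irradiation), 1409 to 2319 (35 against 15 d), 3178 to 6205 and 4702 to 7379 (removed against kept at 15 and 35 d), 125 to 288 and 10270 to 12198 (DMSO culture), 5237 to 8367 and 754 to 1229 (KU60019 and DMSO arms at 15 d) and 629 to 2513 and 10631 to 12243 (arms at 35 d). The numbers of lists called with an estimated correlation were 1 at 15 d, 0 at 35 d, 0 and 3 after removal, 5 after irradiation, 2, 0 and 3 for the differences and 7 and 1 for DMSO culture. Fry, which tests each list by itself, called 12, 21 and 20 lists for 15 d plus removal, 35 d plus removal and DMSO 35 d plus removal against 15 d. Leaving out 1 library, 15 d plus removal had 3 to 9 lists called, the fewest without KU60019 S12_716. The correlation with the irradiation effect was 0.61 for 15 d with the shared DMSO 15 d control, 0.61 for genes of at least 5 CPM and 0.28 against the mean of the 4 DMSO groups, 0.68 and 0.55 for 35 d against DMSO 35 d and that mean, and 0.58 for 35 d plus removal against that mean. With the replicate number as a block, KU60019 15 d, whose numbers pair by the rule, had 5561 genes changed, and the block moved no count of genes by over 1.5 times. Elsewhere the shared numbers do not pair the samples by that rule, 13 of 27 libraries correlated best with their own number, and same-numbered pairs had a mean r of 0.05 (-0.45 to 0.43). In the added arms the block ended the call of matrix genes for KU60019 at 35 d (adjusted p = 0.0551). In the simulation 10.4% of genes changed 1.5-fold were recovered.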

Other observations

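Tests of lower Atm by length-corrected fit and median of matched genes and of a lower share of fibroblasts were chosen after the values were seen. The matched genes, further Schwann markers and splits were set before their results. Atm RNA was lower in 4 of the 5 main comparisons, and Atm is long. A trend of level with gene length as the whole source is argued against in 3 of these, where Atm still passed with the trend removed (15 d plus removal -1.82, adjusted p = 0.00103, 35 d plus removal -1.19, adjusted p = 0.0116, irradiation -1.28, adjusted p = 0.010). At 15 d the fold change went from -1.32 ± 0.42 to -0.94 ± 0.36 and the call ended at adjusted p = 0.0502, a move of 0.37, between the 2 SEs, so length and a change of Atm cannot be told apart there. Among 200 protein-coding genes nearest to Atm in length and level, up to 19% lay below it in a comparison, so a shift shared by such genes, a wording chosen after that value with its bounds kept, may account for part of it. Their median was -0.49 at 15 d, -0.37 at 15 d plus removal and -0.40 after irradiation. At 35 d plus removal it was 0.32 (95% interval 0.13 to 0.45), with 12.5% below Atm. That median argues against a shared shift there. Elsewhere a shared shift stays open. An effect of ATM inhibition on Atm RNA was not tested apart from these.

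Sox10, Ngfr, Erbb3, Cdh19 and Foxd3, all Schwann cell genes, were higher in KU60019 35 d than in DMSO 35 d, unevenly between libraries. Sox10 was 7.69 ± 6.93 against 0.141 ± 0.134 CPM (2.23 ± 1.83 in DMSO 15 d, 4.46 in KU60019 15 d, 3.98 irradiated). Ngfr was 17.5 ± 17.4 against 0.423 ± 0.553 (11.2 ± 10.5, 11.7, 6.48). Much of the gap is thus a loss in DMSO 35 d. Of 20 further Schwann markers, 7 of 17 measured rose and 0 fell, with a median of 1.23 at percentile 99.99 of 10000 random lists matched on level. In DMSO 35 d 4 were at 5 CPM or more. The most abundant in DMSO 35 d, Gpm6b (256 ± 26.8 to 173 ± 33.6 CPM) and Cnp (20.8 ± 2.05 to 25 ± 2.84), did not pass, and Cadm4 (12.2 ± 2.27 to 28.3 ± 13.6) did. Of those risen, Gap43 (6.24 CPM in DMSO 35 d plus removal) and Cadm4 (21.3 in DMSO 15 d plus removal) did not follow Sox10 (0.0129 and 0.0700). L1cam and Gfra3 were low there. A lower share of fibroblasts, which raises all other types alike, cannot be told apart from more Schwann cells: over all 23 measured markers the lower quartile, 1.19, lay below the upper quartiles of endothelial (1.34), macrophage (1.69) and epithelial (1.92) markers. That of 6 markers noticed because they rose, 4.11, lay above them. Schwann cells or their precursors may be the source, which the RNA alone leaves open.

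For the comparisons of 3 with 3 libraries, fitted without the others, the real grouping and the highest other of the 10 splits gave 4742 against 0 genes for KU60019 15 d, 4917 against 0 for 35 d, 6829 against 0 and 5487 against 0 after removal, 4495 against 0 for irradiation, 14 against 0 and 6728 against 0 for DMSO culture, 5358 against 0 and 800 against 0 for the KU60019 and DMSO arms at 15 d and 4375 against 1 and 8406 against 0 for those at 35 d. Only 1 split, the real one, was as large in each, and 10 splits are too few for a share under 0.05.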
